A study of Drosophila melanogaster with 4 samples.

How the data were processed

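The study compared heads of male flies fed sodium valproate with heads of males on normal food on 4 two-colour cDNA arrays (27648 spots each), with the dyes swapped on arrays 3 and 4. Per the series' design text, total RNA came from separate pools of frozen heads, each array held 1 treated and 1 control pool, and the 4 arrays were biological replicates. The samples form a single group of 4 ratios, so that the comparison of treated with control heads is the test of a mean log ratio against 0. Its p-values rest on the spread between these 4 arrays and on a spread pooled over clones.

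The deposited values are 1 log ratio per spot and array, taken here as log2. Per the series' design text, the authors scanned the slides at 10 micrometres, quantified them in GenePix Pro 6.0 and normalised the ratios in Acuity 4.0, ignoring spots under 100 intensity units. They kept spots with under 3% saturated pixels, no bad flag, a regression R2 of at least 0.6 and a signal-to-noise ratio of at least 3, and ran a one-class analysis in SAM 2.21 with 100 permutations. The file holds no intensities, so the signal behind a ratio is unknown here. Its values fell at or below 0 on every array, which a linear ratio cannot do. The base of the log is not stated, nor is the direction of the ratio or whether the swap arrays had been turned. A spot without a value is a spot not listed.

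Spots lie in pairs of 1 clone: all 7609 pairs whose spots are both in the probe annotation share their gene. The values of a pair were averaged. Pearson's r between the spots of a pair was 0.60, 0.69, 0.76 and 0.63 on arrays 1 to 4, with a median absolute difference of 0.181, 0.147, 0.144 and 0.130. Of 13824 clones, 3652 had a value on at least 1 array and 1030 on at least 3 (453 on 4, 577 on 3), the filter that the design text also states. Genes were named from an old platform annotation of the probes, in which 7558 clones have 1 gene symbol, 51 several and 6215 are unnamed. Symbols were updated through the NCBI gene ID to the reference table of assembly Release 6; of the 554 tested clones with 1 symbol, 546 were found, and the others kept the old symbol. No clone with several symbols was named. No coordinates are given because the sources used here give none for the clones.

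Each array was centred on its median before any test. The design fixed before the data were examined kept the values as the authors normalised them. The array medians of 1.01, 1.05, 0.54 and 0.24 then turned out to lie far from 0, and a test against 0 of such values tests the offset of the array. This choice departs from the fixed design and was made before any test was run. The fit on values as deposited is given beside it, and centring had been listed as an alternative. Centring removes any change shared by most clones.

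The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided) per clone, with Benjamini-Hochberg adjustment over the 1030 clones and a threshold of 0.05. It was run for each reading: with the sign of arrays 3 and 4 turned and with the signs as deposited. The spread pooled over clones had 7.54 prior degrees of freedom with the swap arrays turned and 9.87 as deposited. A clone's own 3 or 4 values give fewer, so the pooled spread carried most of the weight in its p. By the rule fixed beforehand, the reading with a mean correlation between orientations above 0 led in the number of genes named, which was the reading as deposited. That is not evidence for it, since a dye effect larger than the treatment effect gives the same sign. No exact sign test of 4 arrays can go below p = 0.125. On simulated clones with the observed spread and pattern of missing values (1030 clones, of which 67, 67 and 66 changed by 0.5, 1 and 1.5 on the log2 scale, each clone and each array independent, with no allowance for the likeness of arrays of the same dye orientation), the test with the swap arrays turned recovered 65.7%, 98.5% and 100% of these, with 3.83% false calls. With the swap arrays as deposited the simulated shares were 65.7%, 100% and 100%. In the simulation 183 clones passed with the swap arrays turned and 184 as deposited, against 1 and 8 in the data. Benjamini-Hochberg adjustment is more lenient when many clones change. These shares therefore do not say what would be found where few clones change.

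Of 23 gene lists fixed beforehand, 11 had at least 5 measured genes and were tested. Clones of a gene were averaged, the same fit was run over 524 genes, and each list's moderated statistics were tested with limma's camera on preranked statistics (preset correlation 0.01, adjusted over the 11 lists). The lists were phototransduction; synaptic transmission; glia; immune effectors; detoxification; fatty acid oxidation and lipid metabolism; oxidative phosphorylation; glycolysis, TCA cycle and sugar metabolism; amino acid metabolism; cytosolic ribosomal proteins; proteasome; chaperones; oxidative stress defence; chromatin; inositol and GSK3 signalling; circadian rhythm; head fat body and sex-biased secreted proteins; antenna and chemosensation; muscle; hemocytes; male reproductive tract; midgut digestive enzymes; and cuticle. Calls of single genes differ between this fit and the fit over clones. The fit over genes averages clones, leaves out unnamed clones and adjusts over fewer tests. With the swap arrays turned, Gs1, Cyp4e2 and Cyp6d5 had the same mean and SD in both fits. Their unadjusted limma p was 4.715e-04, 9.389e-04 and 0.00246 over clones, and 1.01e-04, 9.234e-05 and 9.501e-05 over genes. The number of tests alone thus does not explain their calls. With mean, SD and number of arrays unchanged, only the pooled spread of limma can have changed these unadjusted p. Over genes, chp (-0.14, SD 0.54) and Pis (-0.12, SD 0.24) had like unadjusted limma p, 0.391 and 0.404, despite unlike SD. A gene's own SD thus counted for little in that fit with the swap arrays turned.

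Genes named in the text were chosen by a rule fixed beforehand. Under the leading reading they are the 10 highest and 10 lowest clones with 1 gene symbol, past the threshold and of the same sign on every array that measured them, 1 clone per gene, filled with the smallest p where fewer passed. Under the other reading they are the 3 highest and 3 lowest. To these come up to 4 members of smallest p of each list that passed and of the inositol and GSK3, chromatin, synaptic and detoxification lists. Genes outside the rule are said to have been chosen after their values were seen.

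Alternatives set beforehand were values without centring, scaling, quantile normalisation, clones on all 4 or at least 2 arrays, dye orientation as a second coefficient, a SAM statistic over all 16 sign changes, robust eBayes, gene means, a minimum mean of 0.58, and each array left out in turn. With an array left out, tested clones that kept at least 2 values stayed in, so some rest on arrays of 1 dye orientation. Chosen after seeing the data were centring within each of 32 blocks of consecutive spots, leaving out values whose duplicate spots differ by over 0.5 (678 of 6756), centring on the clones on all 4 arrays, leaving out arrays in the correlations, and adding Cyp12d1-d to the detoxification list.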

Results

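Gene expression was measured in heads of adult male Drosophila melanogaster fed sodium valproate (NaVP), an antiepileptic drug and mood stabiliser that inhibits histone deacetylases, and compared with that in heads of males kept on normal food. Unmated Oregon-R males, 10 to 11 days old and kept at 30 flies per vial, received 0.33 mg/ml NaVP for 3 days. Each of the 4 cDNA arrays set a separate pool of treated heads against a separate pool of control heads, and each such pair counted as 1 biological replicate. NaVP RNA carried the dye Cy5 on arrays 1 and 2 and Cy3 on arrays 3 and 4, the swap arrays. The deposited values are 1 log ratio per spot. Of 27648 spots, 5225, 1322, 3753 and 3199 had a value on arrays 1 to 4, that is 18.9%, 4.78%, 13.6% and 11.6%. Adjacent spots carried the same clone and were averaged, which left 1030 clones with a value on at least 3 arrays. Of these, 554 have 1 gene symbol (524 genes), 2 have several and 474 are unnamed here. All tests below rest on 4 arrays or fewer, and that number limits their precision. Their limma p-values also draw on a spread pooled over clones or genes.

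The series' design text states a SAM analysis that asks which transcripts differ between treated and control heads. The same question was addressed here with limma. Neither the base of the logarithm nor the direction of the ratios is stated. Base 2 was taken from the scanner software's convention, so every fold below depends on it. On arrays 1 and 2, Cy5 over Cy3 and NaVP over normal food are the same ratio. On the swap arrays they are opposite, so each result is given under 2 readings. They are: with the swap arrays turned (values are Cy5 over Cy3) and with the swap arrays as deposited (values are already NaVP over normal food). The turned reading is the likely one by the labels, which list the Cy5 channel first on every array. The design text also writes the scanner wavelengths in the order of Cy5 over Cy3. No label states the order for the value table. Both readings take the ratio on arrays 1 and 2 as NaVP over normal food. The sample titles name normal food first (NF-NaVP). If the ratios ran the opposite way, every "higher" and "lower" below would be exchanged. "Higher" and "lower" mean higher or lower in NaVP heads under the named reading. For a clone with 4 values, the same mean is a dye effect under the other reading. For the 577 tested clones with 3 values, 1 of the dye orientations rests on a single array. The plain mean of such a clone does not cancel the other effect, so it mixes treatment and dye under either reading. These clones include the 1 called below with the swap arrays turned and 7 of the 8 called as deposited. The deposited values were not centred on 0: array medians were 1.01, 1.05, 0.54 and 0.24 on the log2 scale, a 2.01-, 2.06-, 1.45- and 1.18-fold ratio. A test against 0 needs centred values, so each array was centred on its median. This departs from the design fixed before the data were examined. The fit that design describes, without centring, is given in the last paragraph.

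Cyp12d1-d, a mitochondrial cytochrome P450 gene of the kind that responds to foreign compounds (NCBI gene 2768720), was higher in NaVP heads with the swap arrays turned, by 1.62 ± 0.38 on the log2 scale (SD, n = 3), or 3.08-fold. It was the 1 clone of 1030 past the threshold (limma, Benjamini-Hochberg adjusted p = 0.00478) and lay on the same side on the 3 arrays that measured it. Without centring, the fit fixed beforehand, Cyp12d1-d had a mean of 1.70 ± 0.99 (SD, n = 3) but lost the call (limma adjusted p = 0.99972). No clone passed when clones on at least 2 arrays were tested (96 at an unadjusted limma p under 0.05). The tandem neighbour of Cyp12d1-d, Cyp12d1-p, is nearly identical, so the clone may report either copy. The next genes by the naming rule did not pass in the fit of the mean alone, but Gs1, Cyp4e2 and Utx did with dye orientation as a second coefficient (limma adjusted p = 3.881e-04, 0.00278 and 0.0137). Those p-values rest mostly on a spread pooled over clones (76.4 prior degrees of freedom). For Cyp4e2 the Cy5 orientation rests on array 1 alone. In the fit of the mean alone, Gs1, a glutamine synthetase gene, had a mean of 0.62 ± 0.14 (SD, n = 4, limma adjusted p = 0.242). Cyp4e2, another P450 gene, had 0.74 ± 0.23 (SD, n = 3; limma adjusted p = 0.242). On the low side stood Utx, which encodes a histone H3K27 demethylase, at -0.46 ± 0.12 (SD, n = 4; limma adjusted p = 0.329). Below 0 as well were CG5758 at -0.45 ± 0.065 (SD, n = 3) and CG40228 at -0.40 ± 0.13 (SD, n = 3), the last 2 with limma adjusted p = 0.587 and 0.646. At an unadjusted limma p under 0.05 there were 71 clones, 48 higher and 23 lower, where 51.5 are expected if the arrays are independent and nothing differs. A SAM statistic called 7, all higher, and limma called 12 without array 1 and 6 without array 2. Fits with an array left out kept clones with at least 2 values. Without array 1, Cyp12d1-d had values on arrays 3 and 4 alone, both with NaVP in Cy3, so dye and treatment cannot be separated there. Of the 453 clones on all 4 arrays, 79 (17.4%) had the same sign throughout. From the sign agreement within each dye orientation alone, 85.8 (18.9%) are expected if the orientations are unrelated, a value calculated after the counts were seen.

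Genes of detoxification, a list fixed before the data were examined, were higher as a group with the swap arrays turned. Of 11 measured members, 9 had a mean above 0, the list's mean was 0.21 and its median 0.16 (camera test with a preset correlation of 0.01, adjusted p = 0.0217). The call is lost with an estimated correlation (adjusted p = 0.795) and with fry (adjusted p = 0.425), and also when array 2, 3 or 4 is left out (adjusted p = 0.123, 0.0573 and 0.0745). It is lost too without centring (mean 0.40, adjusted p = 0.120) and on genes with a value on all 4 arrays (adjusted p = 0.198). In the fit over gene means, Cyp4e2 (0.74 ± 0.23, SD, n = 3) and Cyp6d5 (0.67 ± 0.45, SD, n = 4) passed over all 524 genes (limma adjusted p = 0.0106 for each), and the same 2 passed adjusted over the list alone. Cyp28d1 had a mean of 0.27 ± 0.53 (SD, n = 4) and GstE12, a glutathione transferase gene, 0.23 ± 0.29 (SD, n = 4), neither past the threshold (limma adjusted p = 0.738 and 0.742). That fit called 5 genes, all higher. The other 3 were Cyp12d1-d, which the list did not hold (it was fixed with Cyp12d1-p), Gs1 and CG9445 (0.79 ± 0.68, SD, n = 4), the last chosen after its values were seen. A gene's own SD counted for little in that fit. Gs1 (0.62, SD 0.14) and Cyp6d5 (SD 0.45) had like unadjusted limma p, 1.01e-04 and 9.501e-05. These calls thus rest mostly on a spread pooled over genes. In the fit of the mean alone over clones, Cyp6d5 and CG9445 did not pass (limma adjusted p = 0.328 and 0.361).

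No other list passed in this reading. The list of glycolysis, the TCA cycle and sugar metabolism had 9 of 12 members above 0 (median 0.13, camera adjusted p = 0.179), oxidative phosphorylation 12 of 15 (median 0.13, adjusted p = 0.188) and amino acid metabolism 5 of 8 (median 0.07, adjusted p = 0.188). Adjusted over the list alone, 1 gene of the glycolysis list passed, Taldo, 2 of amino acid metabolism, Gs1 and pug, and 1 lower of fatty acid oxidation, CG4860. Over all genes only Gs1 did in the fit over gene means, while Taldo and pug passed over all clones with the dye coefficient (limma adjusted p = 0.00767 and 0.0349). For phototransduction (9 genes), synaptic transmission (5), inositol and GSK3 signalling (5), fatty acid oxidation (5), cytosolic ribosomal proteins (9) and head fat body and sex-biased secreted proteins (5) the adjusted p was 0.70, and for antenna and chemosensation (6) it was 0.782. Mean and median differ in sign for the inositol and GSK3 list (-0.022 and 0.0099) and for the antenna list (0.0019 and -0.08). In the inositol and GSK3 list, which holds pathways on which mood stabilisers are known to act, the 4 members of smallest p were Pkc53E (-0.24 ± 0.088), sl (0.19 ± 0.25), Pis (-0.12 ± 0.24) and S6k (0.058 ± 0.30), with n = 4 for Pis and n = 3 for the others. In the synaptic list they were Rab3 (0.23 ± 0.31, SD, n = 3), Gad1 (-0.18 ± 0.44, SD, n = 4), the potassium channel gene Sh (-0.16 ± 0.25, SD, n = 4) and Hdc (-0.03 ± 0.46, SD, n = 4). The chromatin list had 2 measured members, Nap1 at 0.22 ± 0.12 (SD, n = 4) and Smr at -0.02 ± 0.22 (SD, n = 3). None of these members of the inositol, synaptic and chromatin lists passed (smallest limma adjusted p = 0.742 in the fit over gene means).

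**Figure D1:**
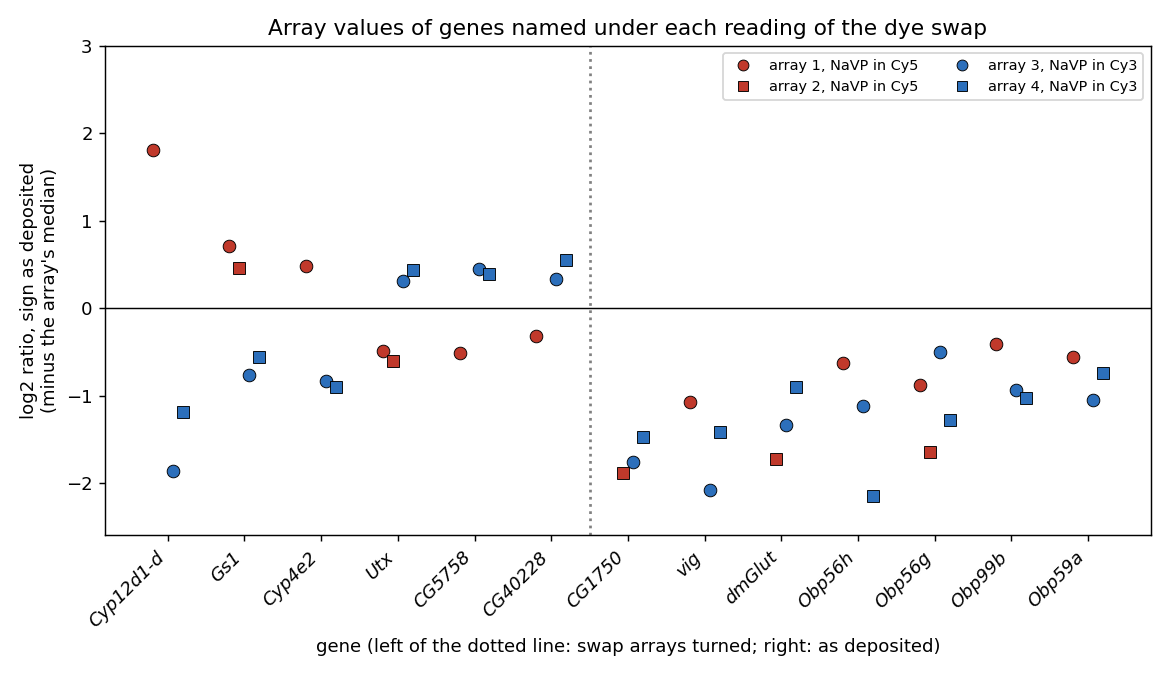
Array values of the genes named with the swap arrays turned (left) and of the genes past the threshold with the swap arrays as deposited (right). Each point is 1 array's log2 ratio minus the array's median, with the sign as deposited; red is NaVP in Cy5, blue is NaVP in Cy3; Cyp12d1-d lies at 1.81 on array 1 and at -1.87 and -1.19 on arrays 3 and 4, while CG1750 lies at -1.88, -1.75 and -1.47 on arrays 2, 3 and 4.

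Under the reading as deposited, 8 clones of 7 genes passed the threshold in the limma fit of the mean alone, and all 8 were lower on every array that measured them. The lowest was CG1750 (NCBI gene 43699), at -1.70 ± 0.21 (SD, n = 3; limma adjusted p = 9.297e-05), a 3.25-fold difference. It was followed by vig, which encodes an RNA-binding protein found with the RNA interference complex, at -1.52 ± 0.51 (SD, n = 3; limma adjusted p = 0.00155). Then came dmGlut, a glutamate transporter gene, at -1.32 ± 0.41 (SD, n = 3; limma adjusted p = 0.00192). The other 4 genes encode odorant-binding proteins, small secreted carriers of hydrophobic molecules. They were Obp56h at -1.30 ± 0.78 (SD, n = 3), Obp56g at -1.08 ± 0.49 (SD, n = 4), Obp99b at -0.79 ± 0.34 (SD, n = 3) and Obp59a at -0.79 ± 0.25 (SD, n = 3). Their limma adjusted p ran from 0.00582 to 0.0483. A second clone of dmGlut also passed, at -1.40 ± 0.81 (SD, n = 3; limma adjusted p = 0.0155). Second clones of the other genes did not: -0.05 ± 0.33 for vig (n = 3), -0.10 ± 0.20 for Obp56g (n = 4), -0.47 ± 0.47 for Obp56h (n = 3) and -0.50 ± 0.77 for Obp59a (n = 3). With the dye coefficient the second clone of Obp56h passed as lower (-0.53, limma adjusted p = 0.0221). That of Obp59a passed instead as higher with the swap arrays turned (0.61, limma adjusted p = 0.009). Without array 3, 3 clones passed; without array 4, 5 did; and without array 1, 19 did. The count was 4 with discordant duplicate spots left out and 24 when clones on at least 2 arrays were tested, and 5 of the 8 clones passed as lower without centring.

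No gene higher in this reading passed in the limma fit of the mean alone, and a SAM statistic called 9 clones, all lower. With the dye coefficient all the genes named in this paragraph passed, ND-ASHI and the others on the high side (limma adjusted p from 0.00737 to 0.0407) as well as ssp, RpS15Ab and CG3301 (7.367e-04 to 0.0163). Block centring gave 3 higher clones in limma. In the fit of the mean alone, the 10 named by the rule had means from 0.38 to 0.52 and limma adjusted p from 0.127 to 0.198. They were ND-ASHI, a subunit of respiratory complex I, at 0.47 ± 0.093, the ribosomal protein gene RpL27 at 0.47 ± 0.17 (SD, n = 4 for each). Next came the chitinase gene Cht6 at 0.43 ± 0.15, the sterol-binding protein gene Npc2a at 0.39 ± 0.16 and thoc7, of the THO complex of mRNA export, at 0.46 ± 0.33 (SD, n = 4 for each), with CG14327, CG10553, CG3448, CG32638 and CG2267. The clones of ND-ASHI, CG10553, CG32638 and Npc2a lie in the same block of spots, so they may share a position offset. Block centring lowered each of them by the same amount, as it must for clones of 1 block with values on all 4 arrays. The equal shift therefore does not test a shared offset. ND-ASHI fell to 0.34 and CG32638 to 0.25 (limma adjusted p = 0.193 and 0.323). RpL27 and Cht6 rose with block centring, and none of the 10 passed with it. The low side was filled with ssp (-0.67 ± 0.37, SD, n = 3), RpS15Ab (-0.59 ± 0.40, SD, n = 4) and CG3301 (-0.55 ± 0.042, SD, n = 3). Each had a limma adjusted p = 0.127. A second clone of RpS15Ab had a mean of 0.18 ± 0.11 (SD, n = 4). At an unadjusted limma p under 0.05 there were 145 clones, 96 higher and 49 lower, and 119 of the 453 clones on all 4 arrays (26.3%) kept 1 sign, where 105 (23.2%) are expected if the orientations are unrelated.

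Of the 11 lists, 0 passed camera with the swap arrays as deposited, and 0 had an unadjusted camera p under 0.05. Fry and the estimated correlation were run on 10 of them, without the inositol and GSK3 list, and 0 passed. Of 9 cytosolic ribosomal protein genes, 8 had a mean above 0 (list median 0.19, camera adjusted p = 0.505), as had 11 of 15 genes of oxidative phosphorylation (median 0.08, adjusted p = 0.505). Adjusted over the list alone, 1 gene passed in each, RpL27 and ND-ASHI, and 1 lower in fatty acid oxidation, yip2. Over all genes none of these did in the fit over gene means, while with the dye coefficient RpL27, ND-ASHI and yip2 passed over all clones (limma adjusted p = 0.00798, 0.00737 and 0.0407). With that coefficient RpL23 of the ribosomal list, chosen after its values were seen, passed as higher too, but it did so under both readings. Of 6 genes of antenna and chemosensation, 4 had a mean above 0 and 2, Obp56g and Obp56h, were called lower, so that the list's mean of -0.11 and its median of 0.14 differ in sign (adjusted p = 0.612). The list of head fat body and sex-biased secreted proteins held 1 gene called over gene means, Obp99b, among 5 (median -0.07, adjusted p = 0.613); adjusted over the list alone, 1 member was higher and 1 lower. The detoxification list had 6 of 11 members above 0 (mean -0.03, median 0.0062, adjusted p = 0.612), so that mean and median differ in sign, with none called in the fit over gene means. Mean and median also differ in sign for fatty acid oxidation (-0.17 and 0.015) and synaptic transmission (0.013 and -0.057). In the detoxification list the 4 members of smallest p were Cyp28d1 (-0.44 ± 0.34, SD, n = 4), Cyp313a1 (0.37 ± 0.27, SD, n = 3), Cyp6a20 (-0.30 ± 0.15, SD, n = 3) and Cyp4e2 (-0.42 ± 0.78, SD, n = 3). The others gave adjusted p from 0.505 to 0.996: fatty acid oxidation 0.505, phototransduction 0.612, glycolysis and amino acid metabolism 0.613 each, synaptic transmission 0.892 and inositol and GSK3 signalling 0.996. In the synaptic list, Hdc, histidine decarboxylase of the photoreceptors' histamine synthesis, had 0.32 ± 0.29 (SD, n = 4), Rab3 -0.26 ± 0.28 (SD, n = 3), Gad1 0.22 ± 0.42 (SD, n = 4) and Sh -0.16 ± 0.26 (SD, n = 4). In the inositol and GSK3 list, S6k had -0.18 ± 0.22, Pkc53E 0.14 ± 0.26 and sl 0.11 ± 0.31 (SD, n = 3 for each), and Pis 0.08 ± 0.26 (SD, n = 4). Of chromatin genes, Smr had 0.17 ± 0.053 (SD, n = 3) and Nap1 -0.06 ± 0.28 (SD, n = 4). The smallest limma adjusted p among these members in the fit over gene means was 0.175, for Cyp28d1. With the dye coefficient Cyp28d1 passed as lower (-0.44, limma adjusted p = 0.015).

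The remaining 12 lists had too few measured genes for a test: 3 of glia; 2 each of proteasome, oxidative stress defence, chromatin, muscle and midgut digestive enzymes; 1 each of immune effectors, chaperones, circadian rhythm, male reproductive tract and cuticle; and none of hemocytes. Of these, Gs1 of the glia list was called higher in the fit over gene means with the swap arrays turned. No other member was called over all genes in that fit under either reading. The midgut genes Jon65Aiv and Jon66Cii had means of 0.51 ± 0.53 (SD, n = 3) and 0.31 ± 0.19 (SD, n = 4) with the swap arrays as deposited; adjusted over the list alone both passed. Jon65Aiv also passed over all clones with the dye coefficient (0.63, limma adjusted p = 0.00452). The circadian neuropeptide gene Pdf, the single measured member of its list, had -0.27 with the swap arrays turned and 0.36 as deposited. As deposited its unadjusted limma p was 0.0316, which adjustment over a list of 1 gene leaves unchanged. Adjusted over all genes it did not pass (limma adjusted p = 0.376).

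**Figure D2:**
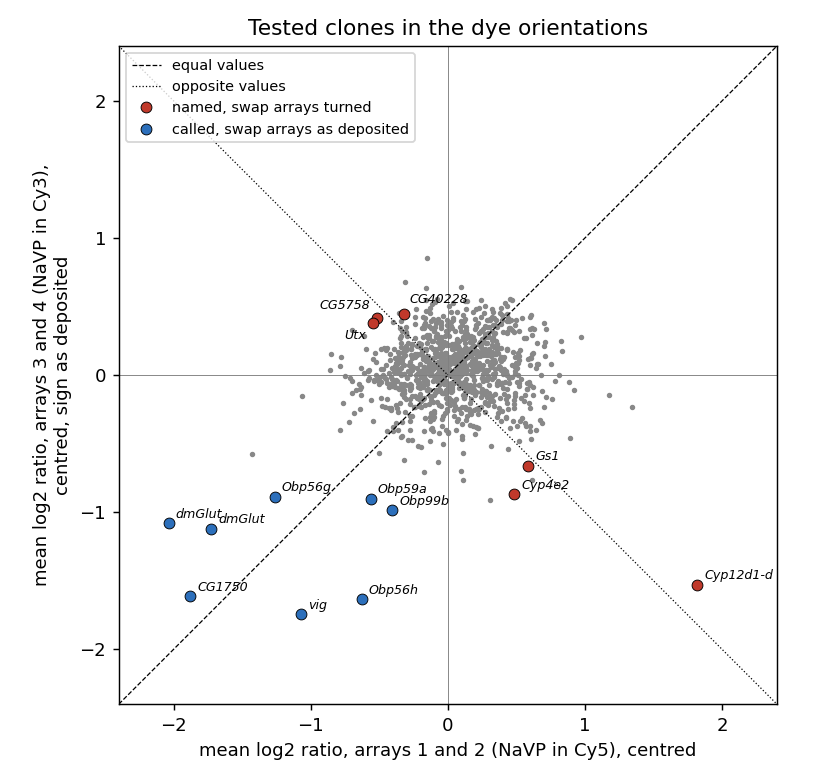
Each of the 1030 tested clones is plotted by its mean centred log2 ratio on arrays 1 and 2 (x axis, NaVP in Cy5) and on arrays 3 and 4 (y axis, NaVP in Cy3, sign as deposited). Cyp12d1-d lies near the dotted line of opposite values, and the 8 clones called with the swap arrays as deposited, in blue, lie where both means are below 0.

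Arrays of the same dye orientation resembled each other more than arrays of opposite orientation. Across the 453 clones with 4 values, which are not independent replicates, Pearson's r was 0.56 between arrays 1 and 2 and 0.35 between arrays 3 and 4. Between orientations it was -0.12, -0.05, 0.17 and 0.28 with the signs as deposited, a mean of 0.07 against 0.46 within orientations. When dye orientation was added to the fit as a second coefficient, so that both the turned and the as-deposited mean were estimated at once, more clones passed in limma. They were 32 with the swap arrays turned (25 higher, 7 lower) and 59 with the swap arrays as deposited (38 higher, 21 lower), with 2 clones in both. These 2 were CG9445 (0.79 turned, 0.55 as deposited) and RpL23 (0.66 turned, 0.52 as deposited), chosen after their values were seen. The 32 held Cyp12d1-d, Gs1, Cyp4e2, Cyp6d5 and Utx (limma adjusted p from 1.074e-14 to 0.0137). That fit pooled the spread over clones with 76.4 prior degrees of freedom, so its p-values rest on a nearly common spread. For a clone on 3 arrays, 1 of the orientations rests on a single array. On the values exactly as deposited, without centring, the counts were 0 with the swap arrays turned (6 clones at an unadjusted limma p under 0.05) and 745 as deposited, 740 of them higher.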

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

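Of 50 values checked for 1 array far from the other 3 (named genes, lists, array medians and clones listed), 2 stood out, where chance alone gives about 5%, or 2.5. With the swap arrays turned, Nap1, a histone chaperone gene, had 0.41 on array 3 and at most 0.17 on the others; the gap took up 0.946 of the whole range. With the swap arrays as deposited, the list of head fat body and sex-biased secreted proteins averaged 0.25 on array 2, above -0.10, the next highest array; the gap was 0.876 of the range. Array 2 lacked a value for Obp99b, a called member of that list.

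The tests by block centring and by second clones were chosen after the result was seen. The sign patterns, the estimated correlation and the correlation between orientations were set beforehand. What each test should show under each explanation was written down only after the results. The first pattern is the higher value of Cyp12d1-d and the detoxification list with the swap arrays turned. Values drifted along the slide, so a position effect was tested by centring each block of consecutive spots. Cyp12d1-d then had a mean of 1.62 (SD 0.20, limma adjusted p = 1.92e-04) and the list a camera adjusted p of 0.0260. These values argue against drift between blocks as the whole cause. An effect on neighbouring spots within a block would remain after this centring, so it was not tested. The list's own correlation stays open, since its adjusted p was 0.795 with the correlation estimated. A dye effect cannot be told apart from the treatment, because the direction of the swap arrays is not stated, and the mean correlation of 0.0712 between orientations does not settle it. Of the 8 sign patterns of 4 arrays, 4 called at least as many clones as the 1 called here, the highest other pattern 8, and 8 patterns are too few for a share under 0.05.

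The second pattern is the 8 clones lower on every array with the swap arrays as deposited. After block centring, 8 of the 8 stayed past the threshold, which argues against drift between blocks as the whole cause. An effect on neighbouring spots within a block would remain after this centring, so it was not tested. The called clone of vig lies next to the low clone of RpS15Ab, and the further clone of neither gene was called. Position at that scale stays open. For dmGlut, a fault of a single spotted clone is argued against by its second clone at -1.40. For vig, Obp56g, Obp56h and Obp59a this stays open. Their further clones had a median of -0.29, against -1.19 for the called clones of these genes. The further clones of vig and Obp56g lay near 0 and those of Obp56h and Obp59a in between. CG1750 and Obp99b had 1 tested clone each, so a fault of a single clone could not be tested for them. A dye effect and the treatment cannot be told apart here either (mean correlation 0.0712). No sign pattern but this 1 of 8 called as many clones, the highest other being 4, and 8 patterns are too few for a share under 0.05.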

How the results depend on the processing

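Tests with block centring, with discordant duplicate spots left out, with centring on clones of all 4 arrays, with Cyp12d1-d added to its list and with arrays left out of the correlations were chosen after seeing the data. The count of 1 called clone with the swap arrays turned stayed at 1 (Cyp12d1-d) with scaling, quantile normalisation, robust eBayes, the minimum mean, block centring, discordant duplicates left out and the other centring. It was 0 without centring, 0 on clones of all 4 arrays (Cyp12d1-d has 3 values) and 0 with at least 2 arrays; the cause of the last was not tested. It was 5 with gene means, 7 with SAM and 32 with the dye term, whose fit removes the other reading's mean from the residual, and 1 to 12 with an array left out (12 without array 1, 6 without array 2). With the swap arrays as deposited, the count of 8 was between 6 and 11 with scaling, quantile normalisation, robust eBayes, gene means, the minimum mean, SAM, block centring (3 of 11 higher) and the other centring. It was 745 without centring (740 higher), where the array offsets are tested, 1 on clones of all 4 arrays (7 of the 8 have 3 values), 24 with at least 2 arrays, 59 with the dye term (38 higher), 4 with discordant duplicates left out, and 3 to 19 with an array left out (3 without array 3, 5 without array 4, 19 without array 1). Except where stated, the cause was not tested. The mean correlation between orientations of 0.0712 lay between 0.0462 and 0.135 in the other calculations and between -0.08 and 0.23 with an array left out, so that without array 4 the sign that chose the leading reading turned. The number of lists that passed as deposited was 0 in every alternative but the other reading, where it was 1. With the swap arrays turned it was 1, and 0 without centring, with genes on all 4 arrays, with an estimated correlation, with fry and with the other reading, and 0 to 1 with an array left out. The detoxification list's mean of 0.21 was then 0.40 without centring (adjusted p = 0.120) and 0.24 with genes on all 4 arrays (5 members, adjusted p = 0.198), was 0.19 to 0.24 with an array left out (call kept only without array 1), and was 0.21 with an estimated correlation (adjusted p = 0.795) and with fry (0.425). With Cyp12d1-d added it was 0.33 (camera adjusted p = 5.276e-05). That gene was added after its clone was seen to be called, so the rise was fixed in advance and is no support for the list. Under the other reading the list's mean was -0.0347, turned in sign. So were Cyp12d1-d (-0.41), Gs1 (-0.0372), Cyp4e2 (-0.42), CG5758 (0.11) and CG40228 (0.19). Genes named as deposited that turned in sign with the swap arrays turned were ND-ASHI (-0.0519), CG10553 (-0.0224), CG3448 (-0.21), Npc2a (-0.12), CG2267 (-0.0182), CG1750 (0.45), vig (0.80), dmGlut (0.17), Obp56h (0.88), Obp99b (0.52), Obp59a (0.41) and CG3301 (0.21); none passed there. Without centring, ssp (0.20), RpS15Ab (0.12) and CG3301 (0.0525) turned in sign, since the offset exceeds their difference. Among called genes, Cyp12d1-d lost its call without centring and Obp56g, Obp99b and Obp59a did too; with an array left out, dmGlut, Obp56h, Obp99b and Obp59a lost it at least once. No gene named by size or p over all clones changed sign with scaling, robust eBayes, the dye term, block centring or an array left out; members named from lists were not refitted. The signal over background behind each ratio is unknown here.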

Other observations

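The genes in this part outside the rule were chosen after their values were seen. With dye orientation in the fit and the swap arrays turned, 19 of the 32 clones past the threshold have a gene. Besides the P450 genes they include Taldo, the transaldolase of the pentose phosphate pathway (0.50, residual SD 0.25, n = 4), Cyt-b5-r (0.43, residual SD 0.11, n = 4) and pug, an enzyme of folate metabolism (0.42, residual SD 0.24, n = 4), all higher, and alpha-Cat, alpha-catenin of adherens junctions, lower at -0.50 (residual SD 0.17, n = 3). Their limma adjusted p ran from 0.00767 to 0.0387 in that fit, and none passed over all clones without the dye coefficient. The same fit with the swap arrays as deposited called yip2, a thiolase gene of fatty acid oxidation (-0.47, residual SD 0.17, n = 3), and rogdi (-0.38, residual SD 0.25, n = 4), both lower, with limma adjusted p = 0.0407 and 0.0416.

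The array medians as deposited were above 0 on all 4 arrays (1.01, 1.05, 0.54 and 0.24), and so did not change sign between the dye orientations. The log ratio followed the spot number on every array, with Spearman's rho across clones of -0.32, -0.25, 0.18 and -0.41 on arrays 1 to 4. Among 26 genes with 2 tested clones, r between the means of the clones was 0.30 with the swap arrays turned and 0.47 as deposited; without the 5 genes of called clones it was 0.41 and 0.23.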
